A study of Mus musculus with 2 samples.

How the data were processed

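The files hold DNase-seq of adrenal gland tissue from male 5xFAD/CAST mice, in 2 libraries that form 1 group. Per the labels they are biological replicates 1 and 2, from different tissue samples and with age ranges of 9 to 12 and 9 to 13 months, under a shared donor entry, so whether different animals contributed rests on the label of biological replicate. Per the labels the reads were placed on mm10. The aligner, the peak caller and their versions are not given in the sources used here, and neither is the sequencing depth.

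Each library came with 4 deposited lists, made from its own filtered alignments and not pooled. The authors' peak lists give a signal per peak, taken here as cut density scaled to library depth. Every value was a whole multiple of 0.00432 in replicate 1 and of 0.00477 in replicate 2 (tolerance 0.05 of a step). The scale of the signal is not stated in the sources, so the depth computed from these steps rests on an assumed scale, and no comparison used it. The peak lists gave no p-value, q-value or summit per peak, and midpoints were used. The deposited FDR tracks give a false discovery rate of the cut density, and only bases at 0.05 or below are listed, 59389549 bases (2.18% of the genome) in replicate 1 and 55290743 (2.03%) in replicate 2. An unlisted base is therefore not a base at 0. The longer peak list of each library reached an FDR of 0.05 and the shorter one, with 106108 and 107752 peaks, an FDR of 0.001. The footprint lists carry a constant in place of a score per footprint, so only their positions were used.

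The longer list was the main one, since the narrower list was to be used and its mean widths of 216 and 201 bp were below the 218 and 203 bp of the shorter list, which is called the stricter list. Peaks of both libraries were merged into regions, and a region was shared when it held peaks of both. Overlaps needed 1 bp and were checked with bedtools 2.31.1, which gave 130693 of the peaks of replicate 1 and 131638 of those of replicate 2 as overlapped. Statistics used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9. Genes were the 21803 protein-coding genes of the basic GENCODE M21 annotation. A promoter was accessible when a peak lay within 1000 bp of any of its TSS positions in both libraries. A region belonged to the gene with the nearest TSS within 100 kb.

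The group has no counterpart, so results describe these 2 libraries, and errors are SDs over both where a value exists per library. Before the data were examined, the comparisons, 24 gene lists, 28 consensus motifs, the alternatives and the rule for naming genes were fixed. The lists covered steroidogenic enzymes, adrenocortical identity and ACTH response, zona glomerulosa, X zone, chromaffin cells, Schwann and glial cells, capsule and stroma, endothelium, macrophages, lymphocytes, erythroid cells, adipocytes, kidney, liver, skeletal muscle, central nervous system, cholesterol synthesis, circadian clock, immediate early genes, glucocorticoid response, housekeeping, transgene source genes, and olfactory and vomeronasal receptors. Lists with 5 or more measured genes, 22 of them, were tested. Named genes are, per list, up to 4 members with the most shared regions and up to 3 with no promoter peak in either library. Beyond the lists they are the 10 genes with the most shared regions, the 5 strongest shared regions by mean rank, and for the library difference up to 4 members with the largest ratio of each list outside the central 95% of random lists. For the olfactory and vomeronasal lists in the promoter comparison no member was named. Some of the members that this rule takes are not named. Further names are marked where they stand, apart from Cyp11b1, named as the paralog beside Cyp11b2.

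Promoter shares of lists were compared with all other genes by Fisher's exact test. The median number of shared regions of a list was ranked among 10000 random lists of the same size, matched on deciles of territory length (permutation test). Both tests were two-sided, with Benjamini-Hochberg adjustment over 22 lists and a threshold of 0.05. Motif matches in the central 150 bp of distal shared regions were compared with windows of equal size 500 bp outside the region and in no peak, which kept 91524 of 95811 regions, by McNemar's exact test with adjustment over 28 motifs. Footprint odds ratios compared bases inside and outside motif matches in the peaks of a library. The intervals of motif ratios and of odds ratios of motifs near gene lists are at 95% and cover counting error only. Those of footprint odds ratios, also at 95%, come from leaving out chromosomes (jackknife). They were computed within each library and do not cover the spread between libraries. For the library difference the median log2 ratio of a list was placed among 10000 random lists matched on signal.

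Tests were checked on simulated data. Random lists of 12 genes were called in 0% of 200 cases for promoters and for regions, and planted lists with tripled regions in 100% of 10. Lists in which every member had a promoter peak were called in 100% of 10, and lists that lost the peaks of 80% of members in 80%. Weaker promoter lists, with a peak at about 90% of members, were called in 0% of 20 when 80 random lists were tested with them. With 2 random lists 45% of 20 were called. All list simulations used the stricter peak list and were adjusted over the simulated lists tested together. Their rates are therefore not the power or error rate of the tests reported here. In the data, full promoter lists of 7, 9 and 10 genes did not pass. A motif planted in 5% of windows was recovered at 5%. Footprints of replicate 2 moved at random within their peaks gave odds ratios from 0.815 to 3.35 where 1 was right, so a version stratified by peak (Mantel-Haenszel) was added after this was seen, which gave 0.860 to 1.49. The list mean in place of the median and the count of repeated 36-base sequences in the strongest regions were also added after the data were seen. The read length was not given, and 36 bases stand in for it.

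The alternatives were 50% reciprocal overlap, the stronger 50% of each peak list, the stricter peak list, promoters of 500 and 2500 bp, all regions within 50 kb, windows of 300 bp, random windows matched on GC in bins of 5%, distal peaks alone for footprints, the union of both lists for the correlation, promoter peaks alone or a median ratio of 0 for the library difference, flanks of 100 kb at Thy1, and each replicate left out. The cut density over Thy1 that was to be ranked is not in the files, and the percent of bases at an FDR of 0.05 or below, minus that of 20 kb flanks, was ranked among 1000 genes of like length in its place. The percent of gene body bases at that FDR was compared with random lists of like length, with and without the bases within 1 kb of the gene's own TSSs. Reads were not available, so copy number, strain alleles and reads of transgene origin were not examined.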

Results

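DNase-seq maps accessible chromatin: DNase I cuts DNA that is not wrapped in nucleosomes, and the density of cuts marks promoters, enhancers and other bound sites. Adrenal glands of male 5xFAD/CAST mice were profiled. 5xFAD is an Alzheimer's disease model with human transgenes driven by a mouse Thy1 cassette, and CAST is a strain derived from wild mice. There was 1 group of 2 biological replicates. Replicate 1 came from mice aged 9 to 12 months and replicate 2 from mice aged 9 to 13 months, so the design holds no contrast between groups and asks which chromatin was accessible in both libraries. The sequencing depth was not given. The values of the deposited signal rise in steps that would give a depth only if its scale were stated, so the effect of depth on precision is unknown. Replicate 1 held 168608 peaks covering 36.4 Mb and 486043 footprints, and replicate 2 held 171869 peaks covering 34.5 Mb and 432742 footprints. Peak strength is the deposited signal, taken here as a cut density scaled to library depth. Its median was 0.588 in replicate 1 and 0.654 in replicate 2. Positions are on mouse build mm10, and gene symbols and models are those of GENCODE M21.

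Most peaks of each library were also found in the other. Of the peaks of replicate 1, 77.5% were overlapped by a peak of replicate 2, and 76.6% in the other direction, 77.1% on average. These are 1 comparison counted from both sides, so no spread is given. Merged over both libraries, the peaks made 203999 regions, of which 127169 were accessible in both, 37060 in replicate 1 alone and 39770 in replicate 2 alone. Peaks with no partner were weaker: their median signal was 0.277 in replicate 1 and 0.310 in replicate 2, against 0.778 and 0.864 for peaks with a partner. Across the shared regions the signals of the 2 libraries had a Spearman rho of 0.971 and a Pearson r of 0.979 on the log2 scale, and 99.4% of regions lay within a factor of 2. These correlations are across regions, which are not independent replicates. With regions found in 1 library also counted, at a signal of 0 in the other, rho was 0.760.

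Promoters took a larger part of the shared regions than of the genome. Regions within 1 kb of a protein-coding transcription start site (TSS) made up 19.4% of shared regions and 1.97% of the genome, a 9.83-fold ratio. Coding exons outside promoters held 3.04% of regions (2.71-fold), introns 38.4% (1.11-fold) and sequence outside protein-coding genes 37.4% (0.611-fold). Away from any TSS by more than 1 kb lay 95811 shared regions, 75.3% of all, called distal below. The X chromosome carried 18.5 shared regions per Mb against 50.3 on the autosomes, and its median signal was 0.632 times the autosomal one in replicate 1 and 0.616 times in replicate 2. On distal regions alone the X to autosome ratio was 0.589 in both libraries. The mice were male, with 1 X chromosome per cell, and neither the signal nor the number of regions was adjusted for copy number. Accessibility per copy was therefore not compared between X and autosomes. The Y chromosome carried 57 shared regions.

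The strongest shared region by mean rank was at chromosome 17, 6430001 to 6430180, at the start of Dynlt1b, a dynein light chain gene, with signals of 56.9 in replicate 1 and 67.2 in replicate 2. The next lay at chromosome 17, 39846781 to 39846920, inside CT010467.1, annotated as ribosomal RNA, with signals of 81.9 and 56.6. It was followed by chromosome 1, 88277521 to 88277760, at the start of Hjurp, which loads the centromeric histone CENP-A (39.2 and 42.8). The fourth, at chromosome 9, 123461901 to 123462140, lay inside Lars2, the mitochondrial leucyl-tRNA synthetase gene (54.8 and 37.0), and the fifth, at chromosome X, 169997881 to 169998200, inside Mid1 (34.8 and 39.2). Sequence repeated elsewhere in the genome was common among them. Of the 36-base sequences in the Mid1 region 100% occurred at another position, and so did 81.9% in CT010467.1, 54.5% at Dynlt1b, 47.3% in Lars2 and 0% at Hjurp. In 500 shared regions drawn at random the mean was 1.18% and the median 0%.

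Genes of steroid hormone synthesis stood in dense clusters of accessible regions. Cyp11a1, which makes the first cut of the cholesterol side chain (ENSMUSG00000032323.13, chromosome 9, 58006411 to 58027023, plus strand), was the nearest TSS of 29 shared regions. Its promoter signal was 6.79 ± 0.122 (mean ± SD, n = 2, as for the other promoter signals). Star, which carries cholesterol into mitochondria (ENSMUSG00000031574.8, chromosome 8, 25806555 to 25815982, plus strand), had 23 regions and a promoter signal of 7.55 ± 1.41. Fdx1, the ferredoxin that feeds electrons to mitochondrial P450 enzymes (chromosome 9, 51943306 to 51963556, minus strand), had 22 regions and 8.01 ± 0.0877. Cyp21a1, the steroid 21-hydroxylase (chromosome 17, 34801348 to 34804561, minus strand), had 21 regions and 5.71 ± 1.29. Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase gene (chromosome 3, 98852194 to 98859794, minus strand), had 9 regions but no promoter peak in either library. Over the 11 steroidogenic genes the median was 18 shared regions within 100 kb, against 3 in random lists matched on territory length (permutation test on 10000 random lists, two-sided, adjusted p = 8.80e-04). The neighbouring paralogs Cyp11b1 and Cyp11b2 had 18 regions each and so sit at this median. Neighbours counted as separate members, while random lists drew genes independently, so the p does not cover clustering of list genes. Promoter peaks in both libraries were found for 10 of the 11, against 67.1% of other genes, a difference that did not pass the test (Fisher's exact test, two-sided, adjusted p = 0.149).

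Genes of adrenocortical identity and of the response to the pituitary hormone ACTH all had an accessible promoter, 13 of 13 (Fisher's exact test, adjusted p = 0.0207). Scarb1, the receptor that takes up cholesterol from HDL, led the list with 38 shared regions and a promoter signal of 8.80 ± 0.476. Gata6, a transcription factor gene, followed with 22 regions (8.24 ± 0.980), then Mc2r, the ACTH receptor, with 20 regions and a weak promoter (0.599 ± 0.132). The list median of 9 regions against 5 in random lists did not pass (permutation test, adjusted p = 0.149), while the list mean of 13.1 against 6.46 did (permutation test, adjusted p = 0.0154). The median also passed without replicate 1 (15), without replicate 2 (21), with all regions within 50 kb (14) and in the stronger 50% of peaks (8), but not with the stricter list (6). In the stronger 50% of peaks, and with the stricter peak list, 84.6% of these promoters were accessible and the promoter call was lost.

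All 9 zona glomerulosa genes, those of the aldosterone-making outer layer, had an accessible promoter, without passing the test (Fisher's exact test, adjusted p = 0.0576). Cacna1h, a T-type calcium channel gene, had 21 shared regions, and Cyp11b2, the aldosterone synthase, Wnt4, a signalling ligand, and Kcnk3, a potassium channel gene, had 18 each. The promoter signals were 2.98 ± 0.353 at Cacna1h, 0.691 ± 0.0226 at Cyp11b2, 4.59 ± 0.295 at Wnt4 and 4.42 ± 0.118 at Kcnk3. The list median of 17 regions stood against 6 in random lists (permutation test, adjusted p = 0.00770). That call was lost with the stricter peak list (median 9), with all regions within 50 kb (median 10) and with the list mean (permutation test, adjusted p = 0.0670). Cyp11b2 is also one of the 11 steroidogenic genes. Its gene body was covered at an FDR of 0.05 or below over 98.4% in both libraries, and 15.98% of its 36-base sequences occurred in the neighbouring paralog Cyp11b1. Of the X zone genes, Pik3c2g had 10 regions and a promoter signal of 0.718 ± 0.0236, and Akr1c18, a progesterone-inactivating enzyme gene, had 3 regions and no promoter peak. With 2 genes this list was not tested.

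**Figure D1:**
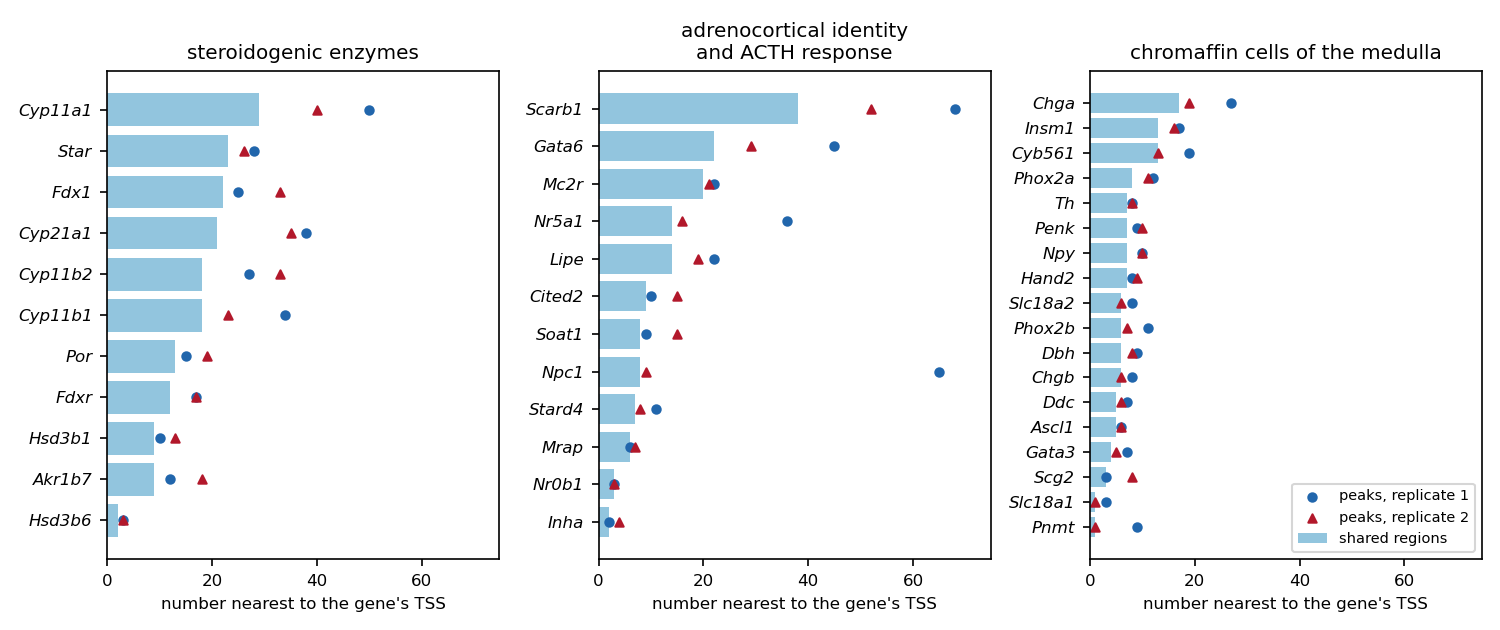
Number of accessible regions per gene in 3 lists, counting regions nearest to the gene's TSS within 100 kb. Bars are shared regions, and points are the peaks of replicate 1 and replicate 2. Of the identity list, 1 gene is not drawn. Scarb1 has 38 shared regions and Cyp11a1 29, against 17 at Chga, the highest of the medulla list.

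Genes of the chromaffin cells, the catecholamine-making cells of the medulla, had a promoter peak in both libraries in 16 of 18 cases and a median of 6 regions, and neither value passed its test. Chga, the chromogranin A gene (chromosome 12, 102554969 to 102565028, plus strand), had 17 shared regions and a promoter signal of 1.33 ± 0.0836. Insm1, a neuroendocrine transcription factor gene, had 13 regions (1.02 ± 0.0458), Cyb561, an electron carrier of secretory vesicles, 13 (4.02 ± 0.556), and Phox2a, a homeodomain factor of the noradrenergic lineage, 8 (1.46 ± 0.195). The share of promoters had an adjusted p of 0.110 (Fisher's exact test). The exceptions, named after their values were seen, were Pnmt, which makes adrenaline from noradrenaline, with a promoter peak in replicate 1 alone, and Ddc, the aromatic amino acid decarboxylase, in replicate 2 alone. Each library alone gave 94.4% and passed the test. The median of 6 shared regions was close to the 5 of random lists (permutation test, adjusted p = 0.819).

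Markers of other cells of the gland ranged widely. All 11 endothelial genes had an accessible promoter (Fisher's exact test, adjusted p = 0.0410), among them Kdr, a VEGF receptor gene, with 24 shared regions (2.02 ± 0.0612), Erg, an endothelial ETS factor, with 17 (0.553 ± 0.0547), and the adhesion genes Pecam1 and Cdh5 with 12 each. This share fell to 63.6% with the stricter peak list and to 54.5% in the stronger 50% of peaks, below the share of other genes there, and the call was also lost with promoters of 2500 bp. The endothelial median was 7 regions against 4 (permutation test, adjusted p = 0.486). Of capsule and stroma genes 9 of 12 had a promoter peak (Fisher's exact test, adjusted p = 0.762), led by Nr2f2, an orphan nuclear receptor, with 31 regions, and the fibroblast genes Pdgfra and Col1a1 with 15 each, while Lum and Acta2 had no promoter peak. Macrophage genes had 6 of 10 (Fisher's exact test, adjusted p = 0.762), with Laptm5 at 12 regions and no promoter peak at Ptprc, Csf1r or Aif1. With the stricter peak list the macrophage share was 20%, fewer than other genes and past the threshold, and in the stronger 50% of peaks 30%, which did not pass. Schwann and glial genes had 3 of 7 (Fisher's exact test, adjusted p = 0.278), among them the myelin gene Mbp and the receptor Erbb3, but not Sox10 or S100b. Adipocyte genes had 5 of 8 (Fisher's exact test, adjusted p = 0.762), with Lep at 21 regions and Pparg at 13, and Adipoq and Cidec without a promoter peak. In none of these 4 lists did the number of regions pass, with permutation adjusted p from 0.508 in adipocytes to 0.990 in Schwann and glial cells.

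Promoters of genes from other tissues were accessible less often. Kidney genes had 1 of 10, Aqp2, the collecting duct water channel (Fisher's exact test, adjusted p = 0.00229), with no promoter peak at Umod, Slc12a1 or Slc34a1. Lymphocyte genes had 1 of 8, the T cell kinase Lck, and erythroid genes 1 of 8 (Fisher's exact test, adjusted p = 0.0103 each), with none at Cd3g of the T cell receptor complex or the globin genes Hbb-bs and Hba-a2. Skeletal muscle genes had 2 of 9, Ckm, the muscle creatine kinase, and Tnnt3, named after its value was seen (Fisher's exact test, adjusted p = 0.0207). Liver genes had 2 of 8, the plasma protein genes Apoa2 and Ttr (Fisher's exact test, adjusted p = 0.0400), and none at the albumin gene Alb. The muscle call was lost with promoters of 2500 bp (55.6%) and without replicate 2 (33.3%), and the liver call with the stricter peak list (25%). With the calls kept, the kidney share was 20% in either library alone and at 2500 bp, and the erythroid share 25% without replicate 1 and at 2500 bp. The liver share was 0% at 500 bp and 12.5% in the stronger 50% of peaks, and the muscle share 11.1% in both and with the stricter list. Central nervous system genes had 4 of 8 and did not pass (Fisher's exact test, adjusted p = 0.523), with Gad1, the GABA-synthesising enzyme gene, at 11 regions and no promoter peak at Gfap or Neurod6. Their share was 12.5% in the stronger 50% of peaks, where it passed, and 25% with the stricter list, where it did not. None of these 6 lists passed for the number of regions, with permutation adjusted p of 0.352 or above. Olfactory receptor genes had a promoter peak in 30 of 1132 (2.65%) and vomeronasal receptor genes in 4 of 329 (1.22%, Fisher's exact test, adjusted p = 5.00e-151), and both medians were 0 regions, against 2 and 4 in random lists (permutation test, adjusted p = 8.80e-04 each). Without replicate 1 the shares were 4.06% and 2.43%, and without replicate 2 3.45% and 2.13%, with the calls kept. Repeated sequence and CAST alleles were not examined at the genes of these lists. A missing peak at duplicated genes, such as globin or receptor genes, is therefore not shown to be closed chromatin.

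Clock, early-response and glucocorticoid-response genes had more shared regions than random lists. Every one of the 13 circadian clock genes had an accessible promoter (Fisher's exact test, adjusted p = 0.0207), with a median of 11 regions against 3 (permutation test, adjusted p = 0.00147). Arntl, the clock activator BMAL1, had 31 regions (12.9 ± 2.08), Per1, a clock repressor, 20 (23.3 ± 3.25), Nr1d1, the nuclear receptor REV-ERB alpha, 14 (24.1 ± 1.66) and Npas2 13 (0.936 ± 0.0822). The 7 glucocorticoid-response genes had a median of 28 regions against 6 (permutation test, adjusted p = 8.80e-04): Sgk1, a kinase of salt balance, had 37, Fkbp5, a co-chaperone of the glucocorticoid receptor, 33, Dusp1, a MAP kinase phosphatase, 29 and Klf9 28. All 7 had a promoter peak, as did all 10 immediate early genes, and neither share passed (Fisher's exact test, adjusted p = 0.143 and 0.0576). The immediate early median was 18 regions against 4.5 (permutation test, adjusted p = 8.80e-04), with Fos at 23, Atf3 at 22, Nr4a3 at 21 and Egr1 at 18. The immediate early promoter share, 100% throughout, passed with promoters of 500 bp, in the stronger 50% of peaks and with the stricter list. Per1 belongs to both the clock and the glucocorticoid list.

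Cholesterol synthesis genes had an accessible promoter in 15 of 16 (Fisher's exact test, adjusted p = 0.0537). Dhcr7, the last enzyme of the pathway, had 20 regions (23.8 ± 2.99), Cyp51 12 (7.15 ± 0.161), Sqle 10 (8.57 ± 1.30) and Insig1 9 (19.2 ± 0.286). Their median of 6.5 regions against 4 did not pass (permutation test, adjusted p = 0.149). The promoter share passed with promoters of 500 bp, in the stronger 50% of peaks and with the stricter list (93.8% each), and without replicate 1 (100%). The median passed without replicate 2 (10.5) and in the stronger 50% of peaks (5). Housekeeping genes had 12 of 12 promoters (Fisher's exact test, adjusted p = 0.0289) and a median of 7 regions against 2.5 (permutation test, adjusted p = 0.00377), with Ywhaz at 31, Actb at 13 and Eef1a1 at 12. Their promoter call was lost with promoters of 2500 bp.

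**Figure D2:**
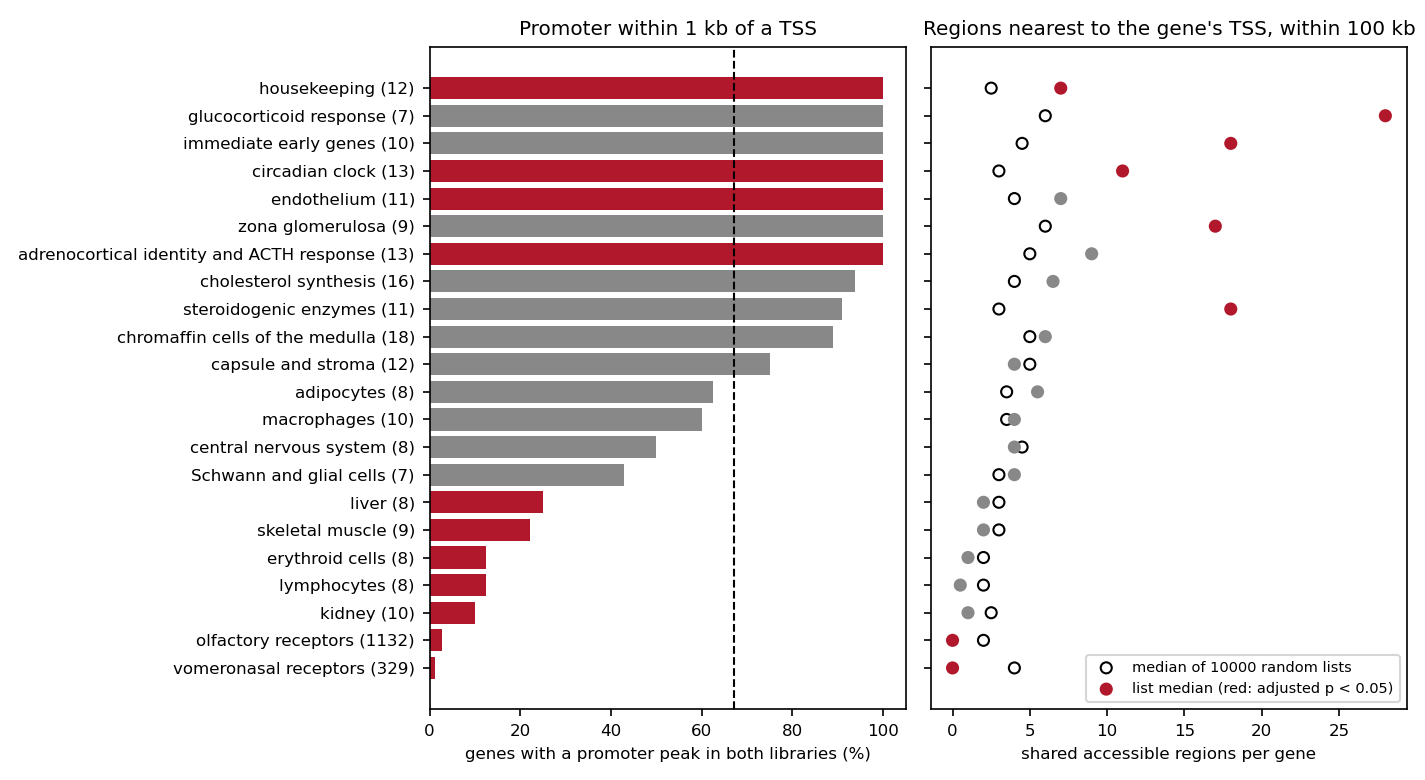
Promoter accessibility and number of regions for 22 gene lists, with the number of measured genes in parentheses. Left, percent of genes with a promoter peak in both libraries, with the share of all protein-coding genes, 67.2%, as a dashed line; right, median number of shared regions per gene (filled) and the median of 10000 random lists (open), in red where the adjusted p lies below 0.05. Steroidogenic enzymes reach 18 regions against 3, and glucocorticoid-response genes 28 against 6.

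Among all 21803 protein-coding genes, 14643 had a promoter peak in both libraries, 67.2% (exact Clopper-Pearson 95% interval 66.5 to 67.8). Of the 22 lists tested 4 had more accessible promoters than other genes and 7 fewer, and 6 had more regions than random lists and 2 fewer. The 4 became 2 with promoters of 2500 bp, and 6 with promoters of 500 bp or without replicate 1. A random-list permutation test with 10000 lists cannot give an unadjusted p below 2e-04. Lists of 12 simulated genes with a promoter peak at about 90% of members passed in 0% to 45% of cases, with the stricter peak list. A high share that missed the threshold therefore does not show that a list was like other genes. Among the genes with the most shared regions were Tns1, a focal adhesion protein gene, with 84, Zfp957 with 73, Gramd1b, a carrier of cholesterol between membranes, with 70, the histone deacetylase gene Hdac4 and Zmiz1 with 64 each, Foxp1 with 62, the potassium channel gene Kcnma1 with 61, Zbtb20 with 59, and Tbx3 with 58. Of those named, all but Zfp957 had a promoter peak in both libraries, and Zfp957 had one in replicate 2 alone, with 11.3% of its gene body at an FDR of 0.05 or below in replicate 1 and 50.03% in replicate 2.

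Mouse genes of the transgene source list were accessible as well, among them App with 17 shared regions and Thy1 with 13. Their promoter signals were 5.60 ± 0.465 and 9.08 ± 0.440. The transgenes are human, and of these 2 genes Thy1 is the one that lends them mouse sequence. Thy1 (ENSMUSG00000032011.5, chromosome 9, 44043384 to 44048579, plus strand) was covered by bases at an FDR of 0.05 or below over 75% of its length in replicate 1 and 74.7% in replicate 2, and the 20 kb on either side over 13.0% and 15.05%. Exon 3, 44046614 to 44046952, had 0% in both libraries, and exons 1 and 2 had 100%. Sequence of the mouse Thy1 gene is part of the transgenes, so reads from transgene copies and from the endogenous gene cannot be separated in these files. With 3 genes the list was not tested.

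**Figure D3:**
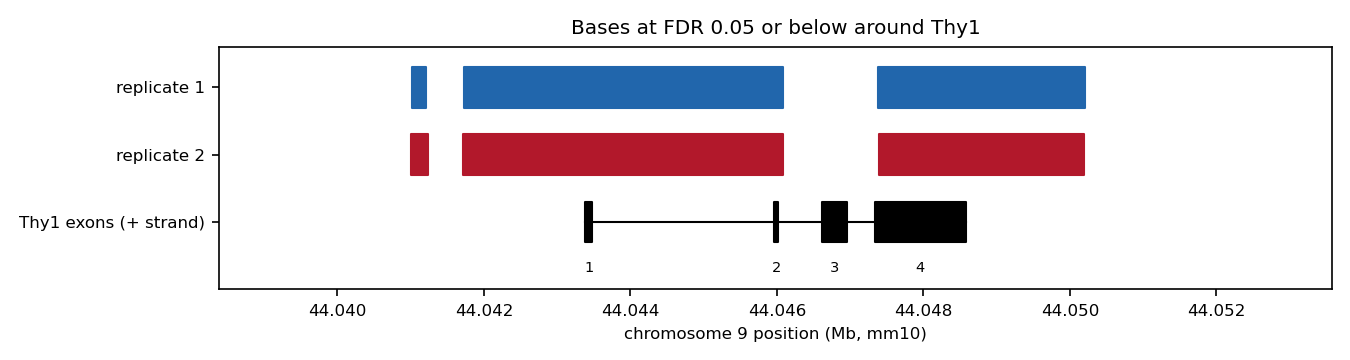
Bases at an FDR of 0.05 or below around Thy1 on chromosome 9 (position in Mb, mm10), as bars for replicate 1 and replicate 2, with the 4 exons of the longest transcript below. Long stretches cover exons 1 and 2 and most of exon 4 in both libraries, and exon 3 lies in a gap of 1299 bp in replicate 1 and 1312 bp in replicate 2.

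Between the 2 libraries, the median log2 ratio of replicate 2 to replicate 1 over shared regions was 0.15 (SD 0.31 across regions). Counted in steps of each library's own signal, the median peak stood at 136 in replicate 1 and 137 in replicate 2. The ratio of 0.15 is thus not separated from the scaling of the signal. Olfactory receptor genes with signal had a median of 0.22 over 166 genes against 0.13 in random lists matched on signal (percentile 100), and vomeronasal receptor genes 0.19 over 68 genes against 0.12 (percentile 98.7). The largest log2 ratios were at Olfr1369-ps1 (1.41), Olfr453 (1.11), Olfr874 (0.97) and Olfr1217 (0.92), and at Vmn2r76 (−1.04), Vmn1r45 (1.03), Vmn1r191 (0.86) and Vmn1r204 (0.82), each resting on 1 shared region. The other 19 ranked lists lay inside the central 95% of random lists, the steroidogenic list at percentile 75.6 (median 0.17), the medulla list at 61.6 (0.15) and macrophages at 96.9 (0.24). With promoter peaks alone, the steroidogenic (99.9), macrophage (97.8) and housekeeping (97.5) lists lay outside. In the stronger 50% of peaks the vomeronasal list lay inside (89.3), and macrophages (99.1) and Schwann and glial cells (98.9) outside. With 1 library per replicate no p can be given, and these percentiles describe the 2 libraries only.

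Binding sequences of steroid-related and general factors were concentrated in distal regions. The extended half-site of the NR5A family, to which the adrenal master regulator SF-1 belongs, occurred in 8.35% of 91524 distal regions and in 1.75% of flanking windows, 4.78-fold (95% interval 4.53 to 5.04). Motifs here are consensus sequences named after a factor or family. A match does not show which protein bound it, and factors with like sequences were not told apart. The palindromic site of the glucocorticoid and mineralocorticoid receptors was 7.69-fold enriched (0.647% against 0.0841%), AP-1, the site of FOS and JUN proteins, 6.65-fold (14.7% against 2.21%), the cyclic AMP response element CRE 4.93-fold, and the plain nuclear receptor half-site 2.69-fold. CTCF, the insulator protein, had the largest ratio, 108-fold (5.33% against 0.0492%), followed by NF-I at 15.8-fold. GATA sites were enriched 1.18-fold. Of 28 motifs 22 were enriched and 3 depleted (McNemar's exact test, two-sided, Benjamini-Hochberg over 28 motifs, all called motifs at an adjusted p of 0.0238 or below). The depleted motifs were SOX (0.800-fold), IRF (0.860-fold) and the PHOX2 dimer (0.302-fold), and PBX/HOX, HNF1 and HNF4 did not pass. Regions held 52.2% GC and flanks 44.9%. Against random windows matched on GC content, NR5A kept a 5.00-fold, AP-1 a 6.56-fold and the glucocorticoid receptor site a 7.07-fold ratio. CTCF fell to 67.1-fold, CRE to 3.44-fold, ETS to 1.43-fold and SP/KLF to 1.28-fold, all still enriched, and GATA was at 1.68-fold. IRF (1.55-fold) turned to enriched, PBX/HOX (1.58-fold) and HNF4 (1.32-fold) became enriched, and PHOX2 (2.29-fold) and NF-Y (0.970-fold) changed side without passing.

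In 20943 promoter regions, CTCF sites were enriched 41.6-fold, CRE 20.4-fold, ETS 13.8-fold, SP/KLF 9.5-fold and NF-Y 6.90-fold over flanks. In distal regions the last 3 were also enriched, at 2.35-fold, 2.46-fold and 1.26-fold. In promoter regions GATA was depleted (0.430-fold, McNemar's exact test, adjusted p = 6.24e-30). The NR5A half-site was at 1.09-fold there and did not pass (McNemar's exact test, adjusted p = 0.292), and the glucocorticoid receptor site was at 1.06-fold (McNemar's exact test, adjusted p = 1.00). The difference between promoter and distal regions was not itself tested.

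Footprints, short stretches protected from cutting inside accessible DNA, overlapped between libraries less often than peaks. Both counts needed 1 bp, but the median width was 10 bp for footprints and 200 bp for peaks. The 2 shares are therefore not on a like scale. Of the footprints of replicate 1, 49.2% were overlapped in replicate 2, and 55.2% in the other direction, 52.2% on average. This too is 1 comparison counted from both sides. Of the footprints 84.4% ± 2.07 lay in peaks, and 80.7% ± 0.856 of peaks held one (mean ± SD, n = 2). NR5A sites were footprinted over 43.7% of their bases in replicate 1 and 43.9% in replicate 2, against 14.3% and 14.0% of other peak bases. This gave odds ratios of 4.67 and 4.79, and of 6.73 and 6.98 when bases were compared within the same peak. CTCF sites reached 46.6 and 40.2 (within peaks 68.2 and 65.9), NRF1, a factor of mitochondrial gene promoters, 71.6 and 74.3, CRE 20.1 and 17.7, NF-I 18.9 and 17.8, SP/KLF 12.8 and 11.6 and AP-1 3.09 and 3.43 (within peaks 3.61 and 4.06). GATA sites were footprinted less than other bases, at 0.50 and 0.427 (within peaks 0.550 and 0.459). Glucocorticoid and mineralocorticoid receptor sites were at 1.05 and 0.945, with 95% intervals that included 1 in both libraries. In both libraries 17 motifs lay above 1 and 3 below with 95% intervals that excluded 1. PBX/HOX and RUNX, 2 of the 3 below, no longer did so in both libraries when compared within peaks. Footprints of replicate 2 moved at random within their peaks gave odds ratios from 0.815 to 3.35 over all peaks and from 0.860 to 1.49 within peaks. Each range spans different motifs, and no motif was compared with its own moved value. Whether a value inside a range stands out is therefore not decided. Random moves also remove any tie of footprints to sequence, including a sequence preference of DNase I cutting, and that preference was not examined. A value outside a range thus does not by itself show binding, or its absence, at the motif. Of 24 motifs with at least 1000 bases, 8 lay above the all-peak range in both libraries and 12 above the within-peak range, with AP-1 among the 12 but not the 8, and GATA lay below both ranges. The CAGCTG E-box (1.25 and 1.28 within peaks) lay inside. REST and HNF1 had too few bases for a usable interval.

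**Figure D4:**
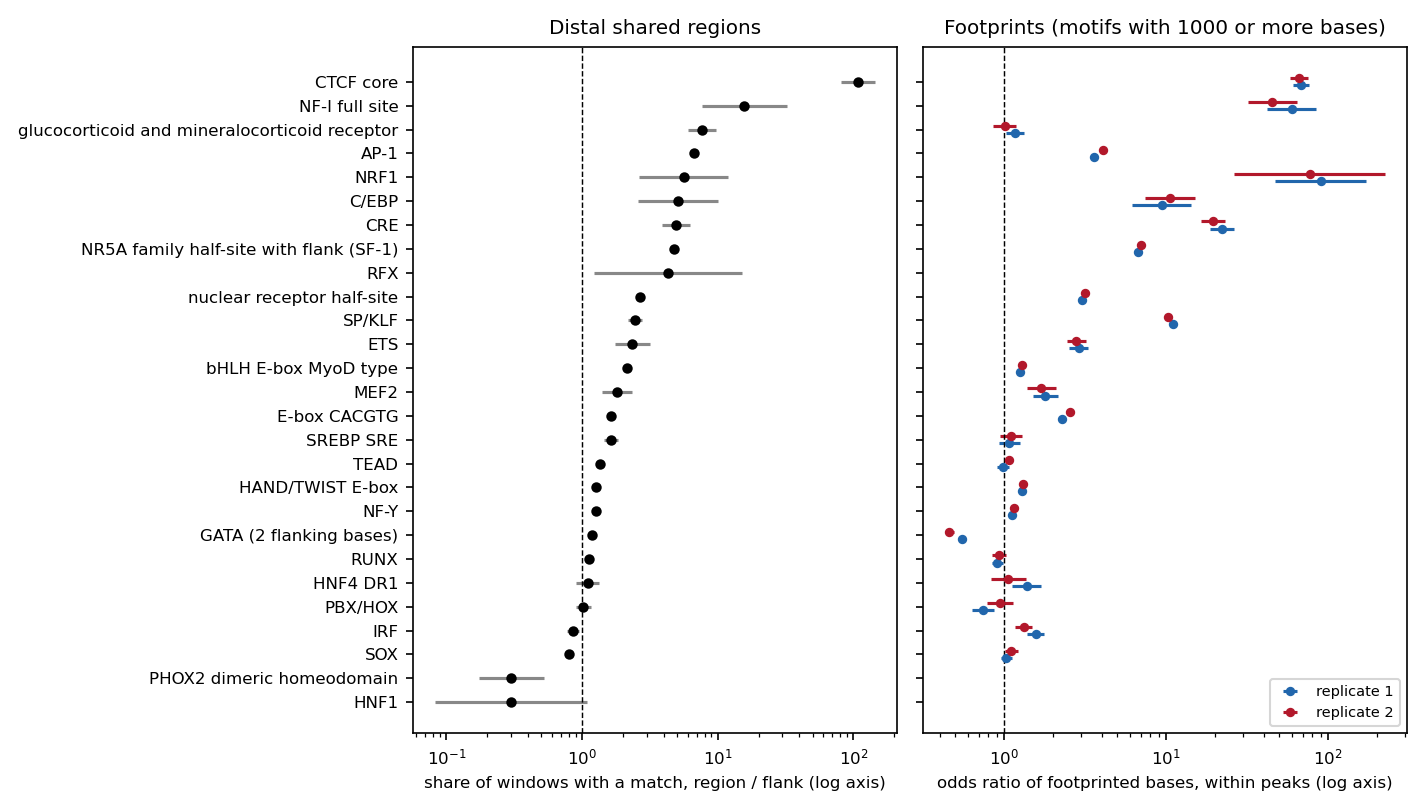
Motifs in distal shared regions and in footprints, both on log axes. Left, share of region windows with a match divided by that of flanking windows, with 95% intervals; right, odds ratio that a motif base is footprinted, compared within peaks, for replicate 1 and replicate 2 with 95% intervals. CTCF is highest among distal motifs at 108-fold, and GATA is the lowest of the footprint odds ratios drawn, at 0.550 and 0.459.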

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

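A comparison of Thy1 with other genes was set before the data were examined, but its measure, the percent of bases at an FDR of 0.05 or below, the tests on Thy1 edges and sites and all tests on Cyp11b2 were chosen after the result was seen.

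Thy1 and Cyp11b2 were widely covered in the FDR tracks, which no comparison of peaks uses. Of 20218 genes of at least 2000 bp, 272 were covered over more than 50% in both libraries, and by mean coverage 7 of them lay above Cyp11b2 and 93 above Thy1. Thy1 was covered over 75% in replicate 1 and 74.7% in replicate 2, and Cyp11b2 over 98.4% in both.

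Coverage of Thy1 minus that of its 20 kb flanks was at percentile 99.3 of 1000 genes of like length in both libraries. It came in 2 long stretches with nearly the same ends, 44041722 to 44046080 and 44047380 to 44050209 in replicate 1, and 44041719 to 44046082 and 44047395 to 44050197 in replicate 2. The known Thy1 expression cassette is an EcoRI fragment of the mouse gene that lacks exon 3 and its surroundings, as known in general and not from the files, and copies of it in the transgenes are a candidate explanation. If its sites are as taken here, all 8 ends lay outside the EcoRI, BanI and XhoI sites of such a cassette by 82 to 107 bp, although BanI has 22 sites in the 18.5 kb searched, exon 3 had 0%, and of 10000 random placements of the stretches 19 matched both EcoRI sites and 1 all 4 sites. Open chromatin of the endogenous gene was not excluded as a part of the signal, since 7.29% of 1234 other long stretches had ends as close between libraries, which is neither rare nor common enough to decide.

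Cyp11b2, the aldosterone synthase (chromosome 15, 74851010 to 74856318), lies beside its paralog Cyp11b1, which was covered over 87.2% in replicate 1 and 27.5% in replicate 2. Reads shared between the pair were tested as a technical source. They do not account for the whole pattern, since the 20 kb beyond Cyp11b2, outside both genes, were covered over 61.8% in replicate 1 and 64.8% in replicate 2, although the 20 kb beyond Cyp11b1 only over 10.9% and 3.71%. Between the genes 53.9% and 85.2% were covered, and 15.98% of the 36-base sequences of Cyp11b2 occurred in Cyp11b1. Extra copies of the locus in this cross could not be tested without copy number and stay open.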

How the results depend on the processing

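The list mean and the footprint odds ratio within peaks were added after the data were seen; the other alternatives were set before. Of the values per list or motif, 513 kept their side of the threshold (21 of them, with the median ratio set to 0, could not move). A further 31 gained a call, 17 lost one and 5 reversed. A value without a call in either setting was counted among the 513 even where its direction changed. Leaving out a replicate could add footprint calls but not remove any of the 20, since a call needed both libraries. Those values, too, were fixed in advance among the 513. Peaks shared moved from 77.1% to 66.3% with 50% reciprocal overlap, 89.8% in the stronger 50% of peaks and 81.0% with the stricter list, and footprints shared from 52.2% to 39.3% with 50% reciprocal overlap. Promoters accessible in both libraries moved from 67.2% to 65.5% at 500 bp, 70.7% at 2500 bp, 60.5% in the stronger 50%, 62.8% with the stricter list and 68.6% to 69.1% without a replicate. The rank correlation moved from 0.971 to 0.760 over the union, where unmatched regions were set to 0, 0.972 with the stricter list and 0.954 in the stronger 50%. Lists outside the central 95% for the library difference went from 2 to 4 with promoter peaks alone. In the stronger 50%, endothelial promoters reversed to 54.5%. Against GC-matched windows IRF reversed to 1.55-fold, and NF-Y (0.970-fold) and PHOX2 (2.29-fold) changed side and lost their calls; IRF was at 1.01-fold with windows of 300 bp. The cause was not tested for any of these. Total counts of calls stayed within 1.5 times: 8 to 13 promoter lists (11 as reported), 7 to 10 region lists (8), 23 to 26 motifs (25) and 18 to 22 footprint motifs (20). By direction, lists with more accessible promoters went from 4 to 2 at 2500 bp and to 6 at 500 bp or without replicate 1, a larger move, those with fewer ranged from 6 to 8 (7), and lists with more regions from 5 to 8 (6). Thy1 coverage above its flanks was 61.4 points with 100 kb flanks and 60.9 with 20 kb. The stronger 50% of footprints was not run, since no score per footprint is given. The REST ratio has no value, since no flank held a match. Depth limits are unknown without read counts.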

Other observations

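The tests of motifs near gene lists were set before their results were seen, and the comparisons of gene body coverage, with and without promoters, were chosen after.

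Gene bodies of steroidogenic genes were covered more widely than those of random lists. The median gene body, by the mean of both libraries, had 31.4% of bases at an FDR of 0.05 or below, against 4.38% in random lists of like length (permutation test, adjusted p = 8.80e-04), with medians of 43.5% in replicate 1 and 27.5% in replicate 2. Star was covered over 76.2% in replicate 1 and 67.4% in replicate 2, Cyp21a1 over 59.0% and 28.9%, and Cyp11a1 over 43.5% and 19.4%, but Fdx1 over 4.48% and 9.66%. Named after their values were seen, Hsd3b6 was covered over 5.91% and 4.23%, Akr1b7 over 7.42% and 10.4%, and Por over 11.3% and 12.3%. Of the 11 genes 3 were covered over more than 50% in both libraries. Without the bases within 1 kb of the genes' own TSSs the median was 32.1% against 0.754% (permutation test, adjusted p = 0.00140), with 45.0% in replicate 1 and 19.1% in replicate 2. Of 20218 genes of at least 2000 bp, 272 were covered over more than 50% in both libraries. That genes of steroid synthesis as a group, though not each of them, are open along their length in this tissue is a hypothesis found and tested on the same data.

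Other lists were also widely covered, with the medians of replicate 1 and replicate 2 in parentheses. Immediate early genes had a median of 56.3% (68.0% and 40.1%, permutation test, adjusted p = 8.80e-04) and housekeeping genes 29.4% (24.3% and 19.3%, permutation test, adjusted p = 0.00147). Genes of adrenocortical identity had 11.9% (18.0% and 7.86%) and of the zona glomerulosa 10.4% (11.1% and 9.66%, permutation test, adjusted p = 0.00342 each). Chromaffin genes had 6.68% against 3.80% in random lists (8.12% and 5.67%, permutation test, adjusted p = 0.268), and kidney genes 0.815% against 3.86% (1.06% and 0.805%, permutation test, adjusted p = 0.0316). Without promoter bases, chromaffin genes at 4.73% against 0.867% (4.94% and 2.42%) and endothelial genes at 4.55% against 1.51% (5.45% and 3.60%) gained a call (permutation test, adjusted p = 0.0395 each). Housekeeping genes kept theirs at 9.40% (5.51% and 4.31%, permutation test, adjusted p = 0.0144). Kidney genes (permutation test, adjusted p = 0.564), cholesterol synthesis genes (permutation test, adjusted p = 0.422) and olfactory receptor genes (permutation test, adjusted p = 1) lost theirs. The tests used the mean of both libraries, and neither library was tested alone.

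Glucocorticoid receptor sites were more frequent near glucocorticoid-response genes. Of 129 distal regions of these 7 genes, 7 held a site, 5.43% against 0.635% of other distal regions, an odds ratio of 8.97 (95% interval 4.56 to 20.1, Fisher's exact test, adjusted p = 6.62e-04 over 30 tests). They belonged to 5 genes. The Per1 region (chromosome 11, 69097021 to 69097280, 1.80 kb from a TSS) held AGAACACGATGTTCC with signals of 21.7 and 25.6, and the Fkbp5 region (chromosome 17, 28420241 to 28420460) held AGAACACCCTGTTCT with 2.77 and 2.89. Klf9 had 1 such region, and Tsc22d3 and Zbtb16, named after their values were seen, had 2 each. All but the Per1 region lay far from the TSS. The distance was 21.4 kb at Fkbp5, 84.2 kb at Klf9 and 29.6 and 37.2 kb at Tsc22d3. At Zbtb16 it was 98.3 and 99.4 kb, close to the limit of 100 kb. Regions of 1 gene are not independent, and an accessible site may or may not have been bound: over all peaks the footprint odds ratio of such sites was 1.05 in replicate 1 and 0.945 in replicate 2. Direct regulation of these genes through accessible receptor sites is consistent with this count, as a hypothesis.

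The same test gave no such result in the other pairs with a stated hypothesis. NR5A sites were found in 17 of 149 distal regions of steroidogenic genes, an odds ratio of 1.43 (0.892 to 2.42, Fisher's exact test, adjusted p = 0.618). AP-1 sites near immediate early genes had an odds ratio of 0.627, on the other side of 1 from the hypothesis, with an interval of 0.362 to 1.17 that includes 1 (Fisher's exact test, adjusted p = 0.549). Distal regions with an NR5A site had a median signal of 0.722 in replicate 1 and 0.874 in replicate 2, against 0.670 and 0.764 without one.

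Npc1, which exports cholesterol from lysosomes (chromosome 18, 12189692 to 12236400, minus strand), was singled out after its values were seen. It was the nearest TSS of 65 peaks in replicate 1 and 9 in replicate 2, with 8 shared regions, and its gene body was covered over 21.0% and 2.82% at an FDR of 0.05 or below. Its promoter signal was 19.9 in replicate 1 and 21.7 in replicate 2. It was not alone among list genes, the next named after their values were seen too: Lss had 34 peaks against 2 (gene body 41.5% against 1.93%), Foxd3 20 against 6 (81.2% against 0%) and Rpl13a 10 against 2 (100% against 9.30%). Rps18 leaned the other way, with 1 against 4 (21.0% against 93.3%). The cause was not tested.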
